A study of Mus musculus with 16 samples.

How the data were processed

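Single cells of tissue given as cortex from 16 mice were sequenced after enrichment for vascular cells, with 1 library per mouse. There were 4 mice in each of 4 groups (APOE3 or APOE4, without or with Alb-Cre), 2 males and 2 females per group. The deposited values are raw UMI counts per gene and cell barcode, not normalised, in tables of 31053 genes. Per the file headers the count tables were made with Cell Ranger 3.0.2, and per the submitters' processing notes reads were mapped to mm10 and Seurat 4.0 was used, for which steps is not given in the sources used here. The deposited barcodes had at least 500 UMIs each and numbered 79797. The annotation release and the treatment of doublets before deposit are not given in the sources used here. Of the gene identifiers, 31011 matched GENCODE vM21 (GRCm38), from which coordinates were taken. Per the labels each library is 1 mouse, and each was counted as 1 replicate. No library was a copy of another of its group, the 24 pairs having a chi-square of 14.3 to 101 per gene over genes with at least 20 counts.

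Barcodes with at least 500 genes and 1000 UMIs were kept (50846). The limit on the mitochondrial share had been set at 10% before the data were examined. It would have kept 2018 cells, because the quartiles of that share were 19.9%, 28.4% and 36.4%, so the limit was moved to 50% from this distribution before any test was run. Per library, the barcodes with the highest scrublet scores were removed as doublets at 0.8% per 1000 barcodes, in all 1909 of 47638 (4.01%), which left 45729 cells. Free RNA was not subtracted. Cells of all mice were clustered together without batch integration in scanpy 1.11.5 with python-igraph 0.11.9 on log-normalised values (3000 variable genes, 40 principal components, 15 neighbours, Leiden resolution 0.3, 14 clusters). Endothelial-like cells were clustered again (2000 variable genes, 20 components, resolution 0.15). The resolutions were not set before the data were examined. For these clusterings 5 and 6 values were looked at, and those used were chosen on marker genes before any test. A cluster was named from markers fixed before the data were examined, with at least 3 among its first 50 genes by fold and no conflict among its first 10, and it otherwise stayed unnamed. A difference from another description of these cells can come from these rebuilt names.

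Counts were summed per mouse and class. A mouse entered with at least 20 cells and a class was tested where each group kept at least 3 mice, which gave 10 classes. Tests were made in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on these sums (TMM factors, filterByExpr with a minimum count of 10, terms for group and sex, Benjamini-Hochberg adjustment over genes within a comparison, threshold 0.05). All adjusted p-values of single genes come from this test unless DESeq2 is named. The 5 comparisons were Cre+ against Cre- within each line, the difference of these 2 effects, and the lines against each other with and without Cre. The sources used here state no test. Gene lists fixed before the data were examined (36, of which 23 are pathways and 13 are other cell types or quality) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 where at least 3 members were measured, 28 of them in endothelial-like cells. Estimated correlation and fry were alternatives. Shares of classes and quality measures were compared by two-sided exact permutation tests of 4 mice against 4 (70 arrangements, smallest p 0.0286). Correlations over mice used 100000 resamples.

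Named genes followed a rule fixed before the data were examined. It took up to 12 called genes higher and 12 lower per endothelial comparison, called members of the fixed pathway lists (up to 10), the smallest unadjusted p to make 10 where fewer than 10 passed, 2 to 4 members of each list that passed, up to 5 called genes per other class and comparison, and Apoe. Outside the rule, Jun, Fos and Dnajb1 in choroid plexus-like cells, the genes called in opposite directions, those that differed by sex or between title-number runs, and those that lead unnamed clusters were chosen after their values were seen. A fold against a group at 0 used a floor of 3 counts over the group. CPM are means over mice with the SD, and errors of log2 fold changes are SE.

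Depth was 19846041 to 40260503 UMIs per mouse, and 290791 to 961362 in endothelial-like cells. The tests were tried on negative binomial counts simulated from the means, dispersions and library sizes of the real genes. In these, 200 genes were changed in APOE4 Cre+ against APOE4 Cre-, and the members of 1 test list were raised 1.5-fold as well. The simulated counts had no effect of sex or run and no correlation between genes. The rates below hold for this number of changed genes and need not hold for fewer. In endothelial-like cells (5114 genes) edgeR recovered 22.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 95.5% of those changed 4-fold, and called 9 unchanged genes. In astrocyte-like cells (8573 genes) these values were 25.4%, 59.7%, 97% and 14, and in choroid plexus-like cells (12152 genes) 49.3%, 77.6%, 97% and 7. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, no sex term, the 8 mice compared alone, title-number runs of 4 mice as a block in place of sex, 1 surrogate variable (sva 3.50.0), each sex alone, other mitochondrial limits, no doublet removal, 1000 genes per cell, thinned sums, capillary-like cells alone, and each mouse left out. Limits of 30% and 40% and none, sums without mitochondrial genes, cells over 10000 UMIs left out, and title numbers 1 to 4 left out were chosen after seeing the data. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9. Unnamed clusters and classes with too few cells were left out of all comparisons.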

Results

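Single-cell RNA sequencing was done on tissue given as cortex from 16 mice. They came from an apoE model in which human APOE3 or APOE4 can be switched on in the liver. ApoE is the main lipid-carrying apolipoprotein of the brain and a major lipoprotein ligand in blood, and APOE4 is the isoform tied to Alzheimer's disease risk. Cre recombinase under the albumin promoter is made in hepatocytes, so a mouse with Alb-Cre (Cre+) makes the human protein in the liver and its Cre- counterpart does not. The 4 groups were APOE3 Cre-, APOE3 Cre+, APOE4 Cre- and APOE4 Cre+, each with 4 mice, 2 male and 2 female. Cells had been enriched for the vasculature by removing myelin, red blood cells, CD11b-positive cells and dead cells. The design asks what liver apoE of either isoform does to cells of the brain's vessels, and whether the isoforms act differently. The libraries held 4165 to 5764 barcodes and 19846041 to 40260503 unique molecular identifiers (UMIs) per mouse. After filtering, 45729 cells remained, 2321 to 3879 per mouse, with a median of 2431 to 3908 UMIs per cell across mice. None of the 44 exact permutation tests of 11 depth and quality measures passed, with 0 at an unadjusted p under 0.05 and a lowest exact two-sided p of 0.0857, where 4 mice against 4 allow no p below 0.0286.

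Choroid plexus epithelial-like cells, which make the cerebrospinal fluid, were the most numerous class with 17008 cells (37.2%), and astrocyte-like cells followed with 10052 (22%). The choroid plexus is not part of the cortex, so the kept cells are not of cortex alone. Smooth muscle-like cells numbered 7959 (17.4%), endothelial-like cells 3452 (7.55%), neural progenitor or neuroblast-like cells 2596, pericyte-like cells 1480, neuron-like cells 1075 and fibroblast-like cells 597. The endothelial-like cells, the main class of the comparisons, gave 121 to 388 cells and 290791 to 961362 UMIs per mouse, and split into 1364 arterial-like and 2088 capillary-like cells. Class shares did not pass in the 4 comparisons of 2 groups, and the difference of the Cre effects was not tested for shares. In 32 exact two-sided permutation tests over 8 classes, 0 passed after adjustment (lowest adjusted p = 0.971), and 0 had an exact p under 0.05. With 4 mice against 4 no exact p falls below 0.0286, so a change in 1 class alone could not have passed the adjustment. These tests do not show that the shares were equal. The lowest exact p, 0.0571, was for smooth muscle-like cells at 13.7% ± 1.85 of kept cells in APOE4 Cre- mice and 19.2% ± 4.18 in APOE3 Cre- mice (SD, n = 4 each). Endothelial-like cells made up 8.61% ± 2.44 in APOE4 Cre+ mice and 5.69% ± 1.27 in APOE3 Cre+ mice (exact permutation p = 0.0857, n = 4 each). Pericyte-like cells made up 7.35% ± 2.62 (SD, n = 4) of the cells in the mice with title numbers 1 to 4, 1 of each group, against 2.23%, 1.63% and 1.14% in the other runs of 4 numbers. Transthyretin (Ttr), the most abundant secreted product of the choroid plexus, was read at 1630 to 13230 CPM in endothelial-like, 1372 to 14650 CPM in smooth muscle-like, 1740 to 11940 CPM in astrocyte-like and 2076 to 26000 CPM in pericyte-like cells.

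**Figure D1:**
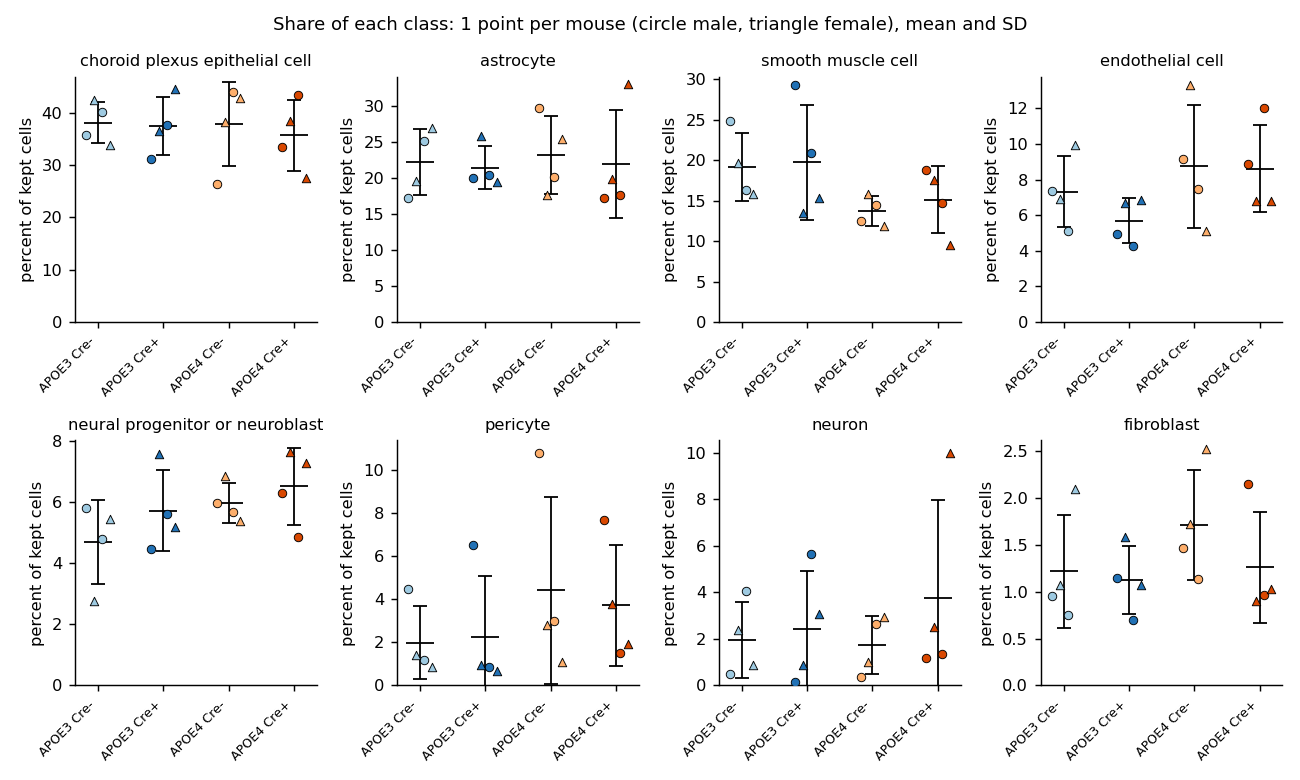
Share of kept cells (percent, vertical axes) held by each of 8 cell classes in the 4 groups. Each point is 1 mouse (circles male, triangles female), the dash is the mean of 4 mice and the bar the SD. Pericyte-like cells range from 0.689% to 10.8% and overlap between all groups.

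The human transgene has no feature of its own in the count tables (0 human APOE features), so the checks that follow concern mouse Apoe (ENSMUSG00000002985, GRCm38 chromosome 7, 19696109 to 19699188). Whether this gene is intact in these lines is not given in the sources used here, and the values below count reads assigned to it. Mouse Apoe was low in endothelial-like cells at 25.9 ± 6.34 CPM in APOE3 Cre-, 35.8 ± 9.48 in APOE3 Cre+, 31.7 ± 18.3 in APOE4 Cre- and 16.2 ± 8.49 in APOE4 Cre+ mice (SD, n = 4 each). Astrocyte-like cells had 68.7 ± 16.3, 85.3 ± 28.0, 99.8 ± 43.4 and 64.4 ± 21.6 CPM in the same order. Apoe passed in no comparison of either class. The lowest adjusted p in endothelial-like cells was 0.302, for APOE4 Cre+ against APOE3 Cre+ (log2 fold change -1.13 ± 0.380, SE). An Apoe UMI was seen in 6.08% of endothelial-like cells (median 1896 UMIs) and 15.7% of astrocyte-like cells (median 1962), against 1.26% of choroid plexus-like cells at a median of 16264 UMIs. Thinned to 1000 UMIs per cell, these shares were 2.96%, 7.83% and 0.0712%. Xist was 724 to 1110 CPM in the 8 females and Y-linked genes 83.9 to 109 CPM in the 8 males, matching the labelled sex of 16 of 16 mice.

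With liver APOE3 on against off, no endothelial gene passed the test. With edgeR, 0 of 5114 genes passed for APOE3 Cre+ against APOE3 Cre-, and DESeq2 called 0. An unadjusted p under 0.05 was found for 190 (3.72%), fewer than chance alone gives on average. The genes with the smallest p that did not pass included Apold1, an endothelial early-response gene, at 202 ± 68.0 CPM with Cre and 465 ± 258 without (log2 fold change -1.17 ± 0.298, adjusted p = 1), and Tfpi, the tissue factor pathway inhibitor, at 4.37 ± 3.42 and 14 ± 6.13 CPM (-1.84 ± 0.559). Hey1, a Notch target, stood at 115 ± 29.4 and 71.7 ± 14.3 CPM (0.65 ± 0.193), the laminin chain Lama3 at 28.1 ± 6.79 and 10.8 ± 2.31 CPM (1.34 ± 0.365), and Sp4 at 26.5 ± 3.61 and 10.7 ± 0.732 CPM (1.26 ± 0.343). Further values that did not pass were Cbx5 0.61, Aamp 0.87, Bmt2 -1.08, Gatm -0.70, 2210016L21Rik -0.93 and Apoe 0.43 on the log2 scale. Among the fixed gene lists, 2 of 28 passed camera with its preset correlation. The immediate early and dissociation response, stress-induced transcription factors that tissue digestion also raises, had a median log2 change of -0.20 over 23 measured members (adjusted p = 0.00803), with Atf3 at -0.89, Klf6 at -0.33, Nfkbiz at -0.75 and Nr4a1 at -0.42. The angiogenesis and Notch list had a median of 0.12 over 25 members, 21 of them positive (adjusted p = 0.0279), with Hey1, Sox18 at 0.38, Jag2 at 0.28 and Unc5b at 0.39. No member of either list passed over all genes tested or adjusted over the list alone. Both list calls were lost with an estimated correlation (adjusted p = 0.545 with an estimated correlation for each). As many list calls came from 26 of 35 splits of the mice, the real one included, counted after the results were seen. The immediate early call also ended on leaving out APOE3 Cre+ replicate 3 (adjusted p = 0.408), the mouse with the lowest mean level of that list, or APOE3 Cre- replicate 3 or 4 (0.165 and 0.0806), and the Notch call without APOE3 Cre+ replicate 1 (0.17) or APOE3 Cre- replicate 2 or 4 (0.0813 and 0.131).

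With liver APOE4 on against off, no endothelial gene passed either. For APOE4 Cre+ against APOE4 Cre-, edgeR called 0 of 5114 genes, and DESeq2 called 0. An unadjusted p under 0.05 was found for 160 (3.13%), again fewer than chance alone gives on average. The smallest p belonged to Spata6 at 49.6 ± 9.92 CPM with Cre and 27.3 ± 6.64 without (log2 fold change 0.94 ± 0.224, adjusted p = 1), followed by Etfa, a mitochondrial electron carrier, at 32.1 ± 8.41 and 56.4 ± 7.39 CPM (-0.80 ± 0.208). Trim5 stood at 26.3 ± 7.63 and 9.57 ± 4.65 CPM (1.23 ± 0.349) and the Wnt ligand Wnt5a at 30.9 ± 19.1 and 55.2 ± 31.8 CPM (-0.88 ± 0.271). Other values that did not pass were Kat2b 0.87, Ushbp1 0.69, Tmem47 1.03, the Wnt receptor Fzd6 0.46, Ralb -0.97, Fam103a1 -0.59 and Apoe -0.86. The heat shock chaperones, which refold proteins under stress, passed camera as a list. Their median log2 change was 0.30 over 16 measured members, 15 of them positive (adjusted p = 2.29e-08), with Hsph1 at 0.82, Dnajb4 at 0.72, Dnajb1 at 0.70 and Hspa1b at 0.61. The interferon response list went the other way with a median of -0.11 over 33 members (adjusted p = 0.014), with Iigp1 at -0.80, Irf1 at -0.55, Gbp4 at -0.47 and Gbp7 at -0.38. No member of either list passed over all genes tested or adjusted over the list alone. The heat shock call was lost with an estimated correlation (adjusted p = 0.0811 with an estimated correlation), and so was the interferon call (adjusted p = 0.895 with an estimated correlation). As many list calls came from 32 of 35 splits of the mice, the real one included, counted after the results were seen. The interferon call also ended without APOE4 Cre+ replicate 2 (adjusted p = 0.348) or APOE4 Cre- replicate 2 or 3 (0.164 and 0.992). The list of choroid plexus transcripts had 4 of 4 measured members positive and did not pass (median 0.51, adjusted p = 0.275).

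The difference between the Cre effects, which tests whether the isoforms act differently, passed for no endothelial gene. By edgeR 0 of 5114 genes passed, and DESeq2 called 0. An unadjusted p under 0.05 was found for 172 (3.36%), again fewer than chance alone gives on average. Ptgs2, the prostaglandin-forming cyclooxygenase 2, had the smallest p, with 39, 81.2, 42.7 and 21.1 CPM in APOE3 Cre-, APOE3 Cre+, APOE4 Cre- and APOE4 Cre+ mice and a log2 difference of -2.11 ± 0.526 (adjusted p = 1). Tfpi had 14, 4.37, 17.5 and 21.4 CPM in the same order (2.18 ± 0.666), and the chaperone Hspa1b 700, 522, 459 and 711 CPM (1.05 ± 0.327). Other values that did not pass were Bmt2 1.45, Gatm 0.96, Lmbrd1 0.77, Cpsf7 1.33, Zfp532 1.62, Csnk1g2 1.10, the thioredoxin reductase Txnrd1 -1.51 and Apoe -1.29. Of the 28 lists, 3 passed camera. The heat shock chaperones had a median log2 difference of 0.48, 15 of 16 members being positive (adjusted p = 7.19e-08), with Hspa1a at 0.77, Cacybp at 0.64 and Hsp90aa1 at 0.56. The caveolae and transcytosis list, coat proteins of the endothelial vesicles, had a median of -0.37 over 13 members (adjusted p = 0.0281), with Cavin1 at -0.54, Ehd2 at -0.49, Cav2 at -0.37 and Ehd4 at -0.60. The immediate early and dissociation response had a median of 0.30 with 21 of 23 members positive (adjusted p = 0.00232), with Zfp36 at 0.73, Nfkbiz at 1.25, Atf3 at 0.94 and Nr4a1 at 0.66. No member of these lists passed over all genes tested or adjusted over the list alone. All 3 calls were lost with an estimated correlation (adjusted p = 0.0967, 0.207 and 0.714 with an estimated correlation, in that order). As many list calls came from 85 of 100 splits of the mice, the real one included, counted after the results were seen. The caveolae call also ended without APOE3 Cre+ replicate 1 or 2 (adjusted p = 0.0517 and 0.138), APOE3 Cre- replicate 4 (0.065), APOE4 Cre+ replicate 2 (0.0622) or APOE4 Cre- replicate 2 or 4 (0.0522 and 0.0891), and the immediate early call without APOE3 Cre+ replicate 3 (0.165), APOE3 Cre- replicate 3 (0.0844) or APOE4 Cre- replicate 3 or 4 (0.137 and 0.0501). The choroid plexus transcripts had 4 of 4 members positive here too and did not pass (median 0.66, adjusted p = 0.308). Across the 5114 genes, which are not independent replicates, the APOE3 and APOE4 effects of Cre were correlated with Pearson r = 0.03 (permutation p = 0.7 over 100 permuted labellings, which gave -0.406 to 0.273).

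With liver apoE on in both lines, APOE4 and APOE3 endothelial-like cells differed in 25 genes, 19 higher and 6 lower in APOE4 Cre+ mice. Ifi203, of the interferon-inducible p200 family, rose to 186 ± 56.7 CPM from 37.1 ± 9.07 (5.10-fold, log2 fold change 2.35 ± 0.305, adjusted p = 4.03e-05, SD, n = 4 each). Its neighbour Mndal, of the same family, rose 4.31-fold (log2 2.11 ± 0.339, adjusted p = 0.00084). The serine incorporator Serinc3 rose to 628 ± 130 from 281 ± 27.5 CPM (log2 1.15 ± 0.157, adjusted p = 6.99e-05). The guanylate-binding protein gene Gbp2b had 0 counts in all APOE3 mice and 29.2 ± 14.7 CPM in APOE4 Cre+ mice, at least 14.4-fold higher from a floor of 3 counts over the group (adjusted p = 0.00084). The calcium-binding S100a16 fell to 77.8 ± 19.9 from 236 ± 35.4 CPM (log2 -1.62 ± 0.211, adjusted p = 4.03e-05), and Pttg1, the securin of cell division, fell to 14.7 ± 27.3 from 136 ± 36.4 CPM (log2 -3.41 ± 0.652, adjusted p = 0.00751).

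Further genes that rose in APOE4 Cre+ endothelial-like cells were the cell cycle inhibitor Cdkn1a (371 ± 189 against 140 ± 25.6 CPM, log2 1.39, adjusted p = 0.0135), Apold1 (log2 1.52, 0.00751), the glucocorticoid-induced Tsc22d3 (1.34, 0.00751), the phosphatase Dusp8 (1.85, 0.0124), Btg3 (1.75, 0.0128), 8430408G22Rik (1.85, 0.00417), Tpm3-rs7 (2.39, 0.00731) and Gm26532 (1.54, 0.015). Genes that fell were desmoplakin (Dsp, log2 -2.96, adjusted p = 0.00862), the lipid carrier Apod (-1.70, 0.0124), Ptgs2 (-1.88, 0.0131) and the mRNA decay factor Zfp36l2 (-1.27, 0.00472). Of the fixed pathway lists, the stress factor Atf3 rose by 1.55 and Tfpi by 2.32 (adjusted p = 0.0314 each). The heat shock chaperones had a median log2 change of 0.39 with 15 of 16 members positive, of which 0 passed over all genes and 2 adjusted over the list alone (camera adjusted p = 4.58e-05), with Chordc1 at 0.65, Hspa8 at 0.55, Hsp90aa1 at 0.46 and Dnaja1 at 0.47. The immediate early and dissociation response had a median of 0.30 over 23 members, 1 higher over all genes and 2 adjusted over the list alone (camera adjusted p = 0.00022), with Cebpd at 1.24, Nfkbiz at 1.07 and Jund at 0.47. The interferon response list had a median of -0.23 with 3 of 33 members positive and 0 passing on either count (camera adjusted p = 2.38e-05), with Ifi27l2a at -1, Ifit3 at -0.74, Iigp1 at -0.81 and Gbp4 at -0.58, while Ifi203, Mndal and Gbp2b are not on that list. Hypoxia and glycolysis had a median of 0.22 over 16 members (camera adjusted p = 0.0184, 0 passing on either count), with Slc2a1 at 0.41, Bnip3 at 0.58, Higd1a at 0.31 and Ndrg1 at 0.25. The cytosolic ribosomal proteins had a median of -0.09 over 81 members (camera adjusted p = 0.0317, 0 passing on either count), with Rpl24 at -0.25, Rpl36 at -0.22, Rps9 at -0.26 and Rpl31 at -0.21. The ribosomal list kept its direction in 32 of 33 alternative settings and passed in 21. All 5 list calls were lost with an estimated correlation (adjusted p = 0.401, 0.578, 0.576, 0.65 and 0.768 with an estimated correlation, in the order given). As many list calls came from 15 of 35 splits of the mice, the real one included, counted after the results were seen. The immediate early call also ended without APOE3 Cre+ replicate 3 (adjusted p = 0.142), the mouse with the lowest mean level of that list. The hypoxia call ended without APOE3 Cre+ replicate 1, 3 or 4 (0.0859, 0.0974 and 0.0613) or APOE4 Cre+ replicate 3 or 4 (0.0968 and 0.142), and the ribosomal call without APOE3 Cre+ replicate 3 or 4 (0.47 and 0.376) or APOE4 Cre+ replicate 2, 3 or 4 (0.111, 0.301 and 0.142). The choroid plexus transcripts, again with 4 of 4 members positive, did not pass (median 0.36, adjusted p = 0.261).

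These calls came from edgeR, and DESeq2 called 17. Leaving out 1 mouse at a time gave 12 genes (without APOE3 Cre+ replicate 3) to 27, with 15 without APOE4 Cre+ replicate 3 or 4. It ended 12 of the 20 named calls, Apold1, Tsc22d3, Dusp8, Btg3, Cdkn1a, Gm26532, Pttg1, Dsp, Apod, Ptgs2, Atf3 and Tfpi, with adjusted p up to 0.216. Each of the 8 mice compared ended at least 1, APOE3 Cre+ replicate 3 ending 9 (adjusted p 0.0659 to 0.136) and APOE4 Cre+ replicate 3 ending 7 (0.0521 to 0.159).

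On GRCm38, Ifi203 (ENSMUSG00000039997) lies on chromosome 1 from 173920407 to 173942672, overlapping the annotated span of Mndal (ENSMUSG00000090272, 173849126 to 173942491), and reads of these related and overlapping genes are uncertain between them. Serinc3 (ENSMUSG00000017707) lies on chromosome 2 from 163623272 to 163645131, Gbp2b (ENSMUSG00000040264) on chromosome 3 from 142594847 to 142619179, S100a16 (ENSMUSG00000074457) on chromosome 3 from 90537254 to 90543151, and Pttg1 (ENSMUSG00000020415) on chromosome 11 from 43420250 to 43426251. Gbp2b has close paralogs, and Tpm3-rs7 (ENSMUSG00000058126, chromosome 14 from 113314608 to 113316754) is a related sequence of Tpm3 with which it can share reads.

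**Figure D2:**
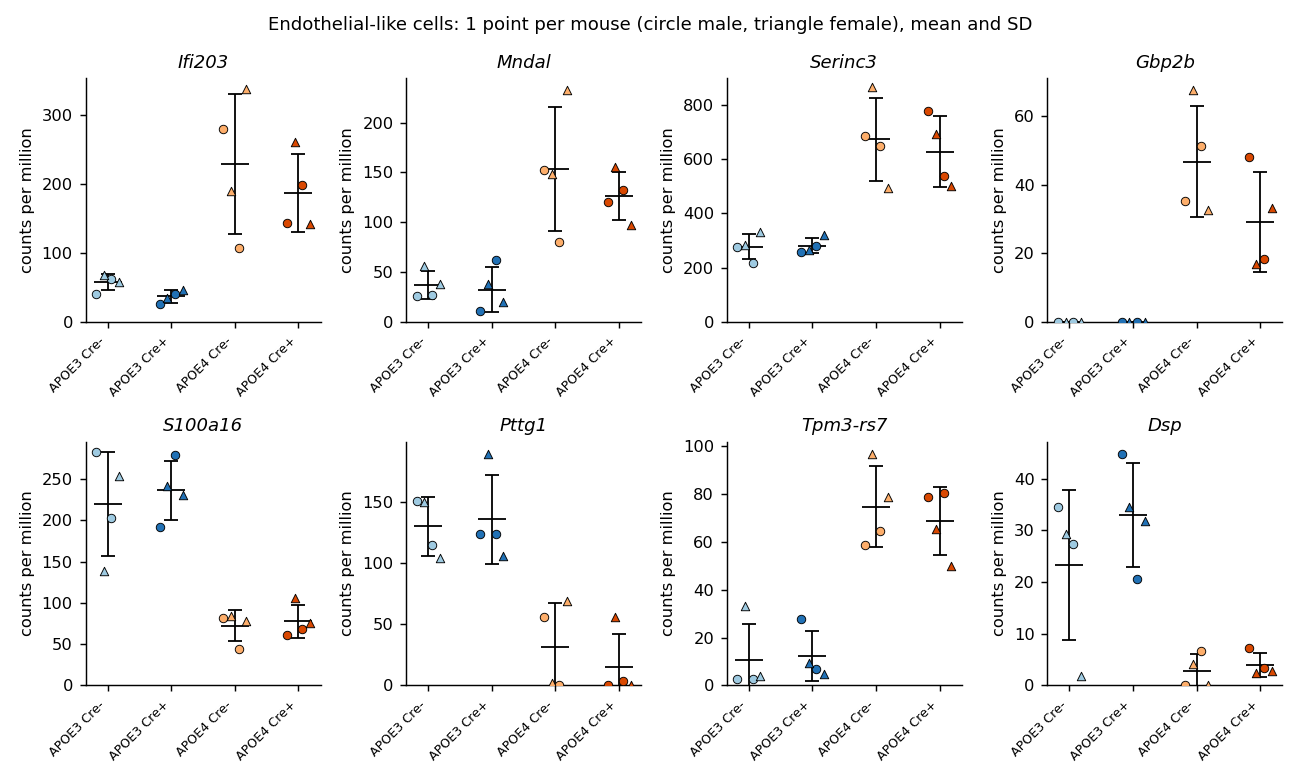
CPM (vertical axes) of 8 genes in the endothelial-like cells of the 4 groups. Each point is 1 mouse (circles male, triangles female), the dash is the mean of 4 mice and the bar the SD. Gbp2b is at 0 in all APOE3 mice, and S100a16 averages 219 and 236 CPM in the APOE3 groups against 72.3 and 77.8 CPM in the APOE4 groups.

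Without Cre, where neither human gene is on in the liver, the lines also differed in 25 endothelial genes, 11 higher and 14 lower in APOE4 Cre- mice. Gbp2b stood at 46.8 ± 16.1 CPM against 0 counts (at least 33.5-fold higher from a floor of 3 counts over the group, adjusted p = 9.67e-06, SD, n = 4). Serinc3 rose to 673 ± 152 from 277 ± 45.6 CPM (2.40-fold, log2 1.26 ± 0.154, adjusted p = 1.09e-05), Ifi203 to 229 ± 101 from 57.5 ± 11.7 CPM (3.94-fold, log2 1.98 ± 0.261, 2.72e-05) and Mndal to 153 ± 62.3 from 37.2 ± 14 CPM (3.98-fold, log2 1.99 ± 0.293, 0.000173). S100a16 fell to 72.3 ± 18.6 from 219 ± 63.2 CPM (log2 -1.62 ± 0.203, adjusted p = 1.37e-05). The non-classical class I gene H2-T22 fell to 11.4 ± 3.99 from 36.3 ± 5.04 CPM (log2 -1.60 ± 0.302, adjusted p = 0.0042), and the semaphorin and VEGF receptor Nrp2 to 17.2 ± 8.85 from 50.4 ± 4.54 CPM (log2 -1.39 ± 0.273, adjusted p = 0.0063).

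Other genes that rose in APOE4 Cre- endothelial-like cells were Tpm3-rs7 (log2 2.82, adjusted p = 0.000238), the p53 target Pmaip1 (2.02, 0.00214), Fam107a (1.78, 0.00724), Crispld1 (1.02, 0.00771), Wnt5a (1.21, 0.0379), Tsc22d3 (0.97, 0.0451) and Crip1 (0.74, 0.047). Those that fell were Gm10036 (log2 -3.09, adjusted p = 0.000757), 4833420G17Rik (-1.99, 0.00156), Gm3716 (-2.88, 0.00191), the actin regulator Eps8 (-2.13, 0.00214), Apod (-1.46, 0.00344), Gm26825 (-3.38, 0.00421), Dsp (-2.97, 0.0112), Lamtor3 (-1.32, 0.0242) and the metallothionein Mt1 (-0.84, 0.0254). Apoe stood at 0.16 (adjusted p = 0.999). Coagulation and fibrinolysis passed as a list and kept its call with an estimated correlation (median log2 change 0.38, camera adjusted p = 1.46e-05, and adjusted p = 0.00769 with an estimated correlation). Its members were positive in 9 of 10 cases, 0 passing over all genes tested and 4 adjusted over the list alone, with the plasminogen activator Plat at 0.70 ± 0.177, S100a10 at 0.89 ± 0.232, von Willebrand factor (Vwf) at 0.62 ± 0.207 and Anxa2 at 0.47 ± 0.190. MHC class I presentation had a median of -0.24 over 19 members, 1 lower over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000749), with H2-T22, H2-Q6 at -0.92, H2-Q7 at -0.80 and B2m at -0.36. The interferon response had a median of -0.13 over 33 members, 0 lower over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0167), with Isg15 at -0.55, Ifi27l2a at -0.77, Trim30a at -0.55 and Ifit3 at -0.46. Hypoxia and glycolysis had a median of 0.26 over 16 members, 0 and 1 passing on these counts (camera adjusted p = 0.00403), with Ankrd37 at 1.30, Bnip3 at 0.80, Slc2a1 at 0.36 and Aldoa at 0.36. Senescence and cell cycle had a median of 0.12 over 11 members, 0 and 1 passing (camera adjusted p = 0.0153), with Ccnd1 at 0.97, Mdm2 at 0.57, Cdkn1a at 0.56 and Igfbp7 at 0.34. Astrocyte reactivity had a median of 0.42 over 10 members, 0 and 4 passing (camera adjusted p = 0.00287), with S100a10, Emp1 at 0.98, S100a6 at 0.87 and Vim at 0.39. The cytosolic ribosomal proteins had a median of -0.11 over 81 members, 0 passing on either count (camera adjusted p = 0.00403), with Rpl13 at -0.23, Rpl12 at -0.22, Rpl29 at -0.21 and Rpl7a at -0.20. These last 6 list calls were lost with an estimated correlation (adjusted p = 0.442, 0.541, 0.457, 0.159, 0.159 and 0.709 with an estimated correlation, in the order given). Over all lists, as many calls came from 9 of 35 splits of the mice, the real one included, counted after the results were seen. Without APOE4 Cre- replicate 4 all 6 ended (adjusted p = 0.0961, 0.44, 0.56, 0.104, 0.0884 and 0.0701). The interferon call also ended without APOE3 Cre- replicate 2 or 3 (0.143 and 0.0827) or APOE4 Cre- replicate 1 (0.299), the senescence call without APOE3 Cre- replicate 2 (0.0607), and the ribosomal call without APOE3 Cre- replicate 2 or 4 (0.655 and 0.362) or APOE4 Cre- replicate 3 (0.393). The separate list of astrocyte transcripts had 7 of 9 members positive and did not pass (camera adjusted p = 0.156). Between the lines with Cre the coagulation list did not pass (median 0.136, camera adjusted p = 0.16, and 0.576 with an estimated correlation). For the difference of the Cre effects its median was -0.305, and it did not pass there either (camera adjusted p = 0.088).

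DESeq2 called 21 genes in this comparison. Leaving out 1 mouse at a time gave 15 genes (without APOE4 Cre- replicate 4) to 30 and ended 11 of the 23 named calls, Pmaip1, Fam107a, Crispld1, Wnt5a, Tsc22d3, Crip1, H2-T22, Gm26825, Dsp, Lamtor3 and Mt1. Leaving out APOE4 Cre- replicate 4 ended 9 of them (adjusted p 0.0505 to 0.723), APOE3 Cre- replicate 4 ended 6 (0.0502 to 0.298) and APOE3 Cre- replicate 1 ended 5 (0.0999 to 0.247), and 15 of the 16 mice ended at least 1.

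The endothelial differences between the lines were shared with and without Cre for 10 genes in the same direction. These were Gbp2b, Ifi203, Mndal, Serinc3, Tpm3-rs7 and Tsc22d3, higher in APOE4 mice, and Apod, Dsp, Pttg1 and S100a16, lower in APOE4 mice. Independent lists of these lengths among the 5114 genes would share 0.0409 higher and 0.0164 lower genes, and the comparisons have no mouse in common. Of the 40 genes called in either comparison, 9 had an unadjusted p under 0.05 for the difference of the Cre effect, and none passed after adjustment. Of all 5114 genes, 172 (3.36%) had such a p. The 40 genes were chosen on the comparisons that make up this difference, so a raised share can come from the choice alone.

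**Figure D3:**
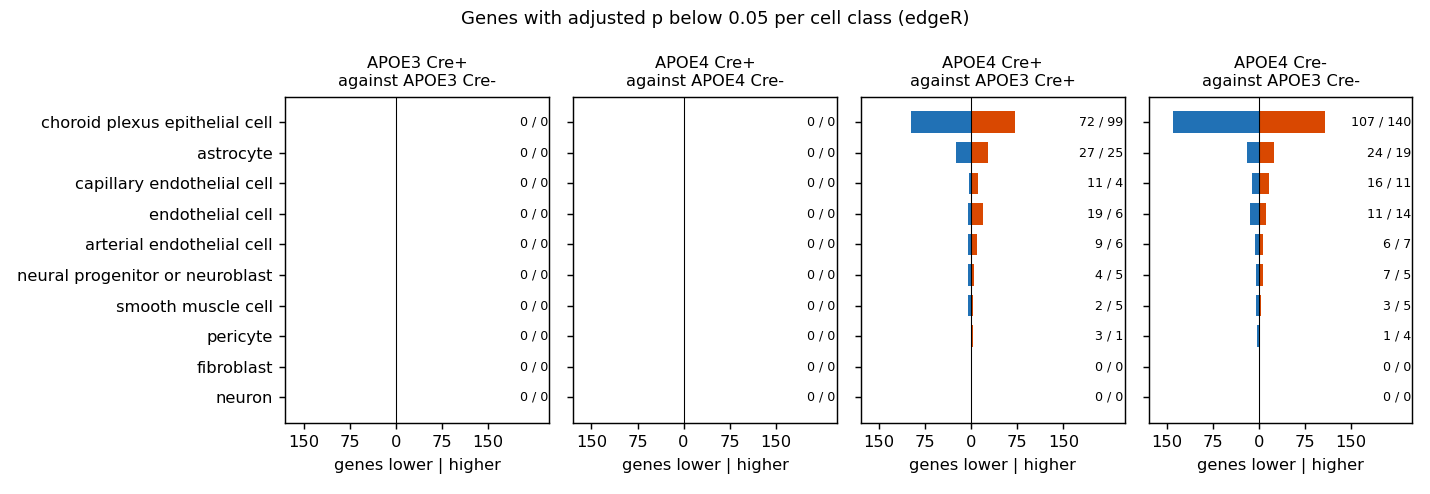
Genes with an adjusted p under 0.05 (edgeR) in each of 10 cell classes for 4 comparisons, as counts of genes higher (right) and lower (left), with both counts printed at the right of each bar. The Cre comparisons of both lines have 0 in every class, while choroid plexus-like cells have 72 higher and 99 lower between the lines with Cre and 107 and 140 without.

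In the 9 other tested classes, which include arterial-like and capillary-like endothelium, no gene passed for liver apoE of either isoform in the fit with sex. By edgeR 0 genes passed for APOE3, for APOE4 and for their difference. The counts at an unadjusted p under 0.05 in choroid plexus-like cells were 177, 630 and 330 of 12152 genes, in astrocyte-like cells 237, 349 and 263 of 8573, in smooth muscle-like cells 141, 240 and 219 of 5952 and in pericyte-like cells 25, 24 and 28 of 878. They were 25, 38 and 25 of 1279 in fibroblast-like cells, 97, 436 and 249 of 6798 in neuron-like cells, 121, 195 and 172 of 4321 in neural progenitor-like cells, 102, 93 and 103 of 2615 in arterial-like cells and 105, 108 and 112 of 3414 in capillary-like cells. DESeq2 called 0 for APOE3 and 5 for APOE4 (3 in choroid plexus-like, 1 in smooth muscle-like and 1 in neural progenitor-like cells), and 1 for the difference. With the title-number runs as a block in place of sex, edgeR called 0 for APOE3, 4 for APOE4 and 1 for the difference. In arterial-like cells the heat shock chaperones passed for APOE4 Cre+ against APOE4 Cre- with 13 of 13 members positive (median log2 change 0.39, adjusted p = 1.13e-09, and adjusted p = 0.0158 with an estimated correlation), 0 passing over all genes and 5 adjusted over the list alone. Their median difference between the APOE4 and APOE3 effects was 0.69 there (adjusted p = 2.29e-10, and adjusted p = 0.0122 with an estimated correlation), with 0 and 3 members passing. In pericyte-like cells the immediate early and dissociation response had 8 of 9 members positive for that difference (median 0.82, adjusted p = 4.69e-08, and adjusted p = 0.00464 with an estimated correlation), 0 passing over all genes and 3 adjusted over the list alone. These list tests were not planned, were picked from many classes, lists and comparisons, and were not repeated on other splits of the mice. Arterial-like cells are part of the endothelial class, where both heat shock calls were lost with an estimated correlation (camera adjusted p = 0.0811 and 0.0967).

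Between the lines, choroid plexus-like cells differed in 171 genes with Cre (72 higher, 99 lower) and 247 without (107 higher, 140 lower), of which 109 were shared in direction. DESeq2 called 255 and 356. Serpine2, a thrombin inhibitor of the serpin family, fell to 3.78 ± 0.582 CPM from 23.2 ± 3.45 with Cre (log2 -2.61 ± 0.127, adjusted p = 8.79e-10) and to 3.36 ± 0.285 from 20.1 ± 1.75 without (-2.67 ± 0.127, 5.48e-10). Hrasls also fell (log2 -3.21 with Cre and -3.08 without, adjusted p = 7.72e-08 and 2.17e-08). The hepatocyte antiprotease gene Serpina1b stood at 8.88 and 8.47 CPM in APOE4 mice with and without Cre against 0.0111 and 0.0501 in APOE3 mice (adjusted p = 1.65e-07 and 2.17e-07), Pik3c2g at 4.24 and 6.47 CPM against 0.0377 and 0.0273, and the meiotic cohesin Rec8 at 2.22 and 3.24 CPM against 0.0377 and 0.0880. Serpina1 genes are near-identical copies, and reads are uncertain between them. On the list of hepatocyte transcripts, 2 of 6 measured members rose in both comparisons and 3 adjusted over the list alone (medians 0.27 and 0.07, adjusted p = 0.00217 and 0.0273, and adjusted p = 0.104 and 0.191 with an estimated correlation). The immediate early and dissociation response was lower in APOE4 choroid plexus-like cells with Cre (median log2 change -0.58) and without (-0.65). Of its 25 members 7 fell in each comparison, 13 and 20 adjusted over the list alone (adjusted p = 1.35e-18 and 6.37e-18, and adjusted p = 0.104 and 0.105 with an estimated correlation). Among them Jun fell to 43.2 ± 12.1 from 127 ± 42.4 CPM with Cre (log2 -1.53, adjusted p = 0.000503) and Fos to 177 ± 69.9 from 402 ± 77.6 (-1.21, 0.0108), and both fell without Cre too. The list of heat shock chaperones was lower there too, 3 of 20 members with Cre and 4 without, 4 and 7 adjusted over the list alone (medians -0.12 and -0.18, adjusted p = 4.23e-05 and 3.58e-12, and adjusted p = 0.326 and 0.0649 with an estimated correlation). Dnajb1 fell to 68.2 ± 9.13 from 162 ± 42.3 CPM with Cre (log2 -1.22, adjusted p = 0.000212), and fell without Cre too.

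Astrocyte-like cells differed between the lines in 52 genes with Cre (27 higher, 25 lower) and 43 without (24 higher, 19 lower), 23 of them shared. The acute-phase serpin Serpina3n, a marker of reactive astrocytes, rose to 41.3 ± 10.7 CPM from 0.676 ± 0.904 with Cre (log2 5.63 ± 0.469, adjusted p = 2.46e-09) and to 48.0 ± 18.3 from 3.14 ± 2.17 without (3.81 ± 0.324, 4.17e-09). Gm49359 rose by 3.98 and 4.33 on the log2 scale (adjusted p = 1.63e-12 and 1.51e-13), and the transcription factor gene Sox11 rose in both comparisons (2.37 without Cre, 8.09e-07). The non-coding Pantr1 fell to 568 ± 50.7 from 1342 ± 262 CPM with Cre (log2 -1.29 ± 0.148, adjusted p = 2.76e-06) and stood at -1.22 without (5.81e-06). S100a10, a member of the astrocyte reactivity list, fell in both comparisons (log2 -3.47 with Cre, adjusted p = 8.47e-06), as did Ddit4l (-1.65 and -2.11). S100a6, also on that list, fell without Cre (log2 -0.709). The reactivity markers named here therefore did not move together, and Serpina3n alone does not show reactive astrocytes. DESeq2 called 48 and 40 astrocyte genes.

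In neural progenitor or neuroblast-like cells, 9 genes differed between the lines with Cre and 12 without, 8 of them shared. Pttg1 rose here, to 178 ± 76.2 CPM from 28.9 ± 9.71 with Cre (log2 2.58 ± 0.407, adjusted p = 0.00164) and to 191 ± 93.1 from 22.8 ± 6.11 without (3.12 ± 0.421, 0.000166), the opposite of its direction in endothelial-like cells. S100a10 fell in both (log2 -1.58 with Cre, adjusted p = 5.99e-06), S100a16 in both (-1.52 and -1.72) and 4933404O12Rik in both (-2.33 and -3.41), while Gm49359 rose in both (2.51 and 2.51) and Fam210b without Cre (1.90, 0.00377). DESeq2 called 12 and 11.

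Pericyte-like cells differed between the lines in 4 of 878 genes tested with Cre and 5 without, sharing Eprs, the glutamyl-prolyl tRNA synthetase, which rose to 252 ± 59.0 from 59.6 ± 25.4 CPM with Cre (log2 2.37 ± 0.409, adjusted p = 0.00214; 1.95, 0.0123 without), and the matrix proteoglycan decorin (Dcn), which fell (-1.90, 0.0143; -1.53, 0.0438 without). The phosphodiesterase Pde10a (2.61, 0.0143) and Cebpd (1.76, 0.0478) rose with Cre, and Mndal (-1.91, 0.0139), Jun (-1.03, 0.0321) and Egr1 (-1.19, 0.0438) fell without Cre. Smooth muscle-like cells differed in 7 of 5952 genes with Cre and 8 without. The non-coding host gene Snhg6 rose in both (log2 1.20 and 1.32, adjusted p = 0.0022 and 0.00059) and Pyurf fell in both (-1.06 and -1.26), Gadd45gip1 rose with Cre (2.14, 0.0004), Arhgap31 (-2.06, 0.0022) fell with Cre, and the mitochondrial mt-Nd3 fell in both (-1.03 with Cre, 0.00855). Without Cre, Tpm3-rs7 (3.28, 0.00668) and the collagen Col3a1 (1.37, 0.0156) rose and Sncg (-0.89, 0.00668) fell. By DESeq2 pericyte-like cells had 3 and 2 calls and smooth muscle-like cells 11 and 8. Fibroblast-like cells had 0 calls by edgeR and DESeq2 (46 and 48 genes at an unadjusted p under 0.05), and neuron-like cells, tested in 13 mice, 0 by edgeR and 1 by DESeq2 in each comparison (301 and 278).

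Arterial-like endothelial cells differed between the lines in 15 genes with Cre and 13 without, and capillary-like cells in 15 and 27. Serinc3 rose to 666 ± 129 from 244 ± 20.4 CPM in arterial-like cells with Cre (log2 1.42 ± 0.185, adjusted p = 2.1e-05) and to 585 ± 157 from 312 ± 45.2 in capillary-like cells (0.93 ± 0.174, 0.00726). Ifi203 rose by 2.01 and 2.72 on the log2 scale with Cre in arterial-like and capillary-like cells (adjusted p = 0.00053 and 0.000211). Both genes also rose without Cre in both classes, and S100a16 fell in both with and without Cre. DESeq2 called 14 and 12 genes in arterial-like and 8 and 15 in capillary-like cells. Across all classes other than the endothelial class as a whole, gene and class pairs called were 273 with Cre and 355 without.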

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

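The tests of chromosome position and the counts over other splits of the mice were chosen after the results were seen, and those of the heat shock list and of the title-number runs before.

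Genes that differed between APOE4 and APOE3 mice, with and without Cre, lay near each other on the chromosomes for those called in both comparisons of 1 class. Of 132 such genes, counting 1 per family and chromosome, 87 had another within 5 Mb, where 10000 random sets had a median of 64 and a highest of 89 (one-sided permutation p = 0.0005). For all 389 called genes the count was 329 against a median of 318 (one-sided permutation p = 0.0752), near its ceiling, and this smaller set was tested after that was known. Genes called in any class or comparison made up 10 of 31 tested on chromosome 12 at 20 to 30 Mb. They made up 12 of 74 on chromosome 1 at 170 to 180 Mb, where Ifi203 and Mndal lie. In the test of all called genes above they were 389 of 10369, and these windows were not tested on their own. By the position of the 132 genes, genetic variants linked to the lines may contribute, as a hypothesis found and tested on the same data. An effect of the transgenes without Cre stays open, untested.

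In APOE4 Cre+ against APOE4 Cre- mice the heat shock chaperones of endothelial-like cells had a median log2 change of 0.30, a list call lost with an estimated correlation (adjusted p = 0.0811 with an estimated correlation). If handling of each mouse's cells were the cause, the list should move together in endothelial-like and smooth muscle-like cells. Over the 16 mice, as deviations from group means, Pearson r was 0.257 (permutation p = 0.335) and Spearman rho 0.282 (p = 0.288), r being 0.162 without the 2 farthest mice and -0.0528 in the 12 mice without title numbers 1 to 4. The value over 16 mice lies between those set for and against handling. The 2 with mice left out lie on the side set against it. Deviations from group means leave out any shift between groups, so this test cannot decide whether handling differed between them. As many list calls came from 32 of 35 splits of the mice, the real one included. Handling was not shown, and handling, chance and an effect of liver APOE4 stay open.

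Mice with title numbers 1 to 4, 1 of each group and all male, stood apart from the other runs of 4 numbers. Pericyte-like cells made up 7.35% ± 2.62 of their cells against 2.23%, 1.63% and 1.14%, their mitochondrial shares were 19.4 to 24.8% against 27 to 34.2%, and the ribosomal pseudogene Gm10076 in endothelial-like cells averaged 1283 ± 170 CPM against 275.8, 231.7 and 319.9. Between runs 1 and 3, both male with 1 mouse of each group, 265 smooth muscle genes passed by edgeR, and library batches that follow the title numbers may be the source. Groups are balanced over the runs, and no biological explanation was tested.

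Single mice stood far from the other 3 of their group in 21 of 312 groups of 4 values (6.73%), where chance gives about 1 in 20. Astrocyte-like cells made up 25.9% in APOE3 Cre+ replicate 3 (others 19.5 to 20.5%) and 33.1% in APOE4 Cre+ replicate 2 (17.3 to 19.9%), which also had 10% neuron-like cells (1.18 to 2.49%). Fibroblast-like cells were 2.15% in APOE4 Cre+ replicate 3 (0.904 to 1.03%), and pericyte-like cells 4.49% in APOE3 Cre- replicate 1 (0.857 to 1.41%) and 6.5% in APOE3 Cre+ replicate 2 (0.689 to 0.953%). In endothelial-like cells of APOE3 Cre- mice, Apoe was 16.4 CPM in replicate 2 (others 28.8 to 29.3), Gatm 378 (155 to 186) and Dusp8 42.2 (10.9 to 14.6) in replicate 3, and Tpm3-rs7 33.2 (2.66 to 3.84) in replicate 4. In APOE3 Cre+ replicate 1, 4833420G17Rik was 36.9 CPM (59.9 to 62.8) and Eps8 36.9 (27.5 to 28.3). In APOE4 Cre- mice, S100a16 was 44.6 CPM in replicate 1 (78.6 to 84.3), Apold1 865 (515 to 553) and Cpsf7 13.1 (24.5 to 26.8) in replicate 2, and Hey1 90.5 (111 to 112) in replicate 4. In APOE4 Cre+ mice, Zfp532 was 13.4 CPM in replicate 1 (23.4 to 25), Hspa1b 955 in replicate 2 (610 to 658), and Pttg1 55.6 (0 to 3.34) and Pmaip1 99.2 (16.7 to 20.1) in replicate 4. Astrocyte-like Apoe was 96.7 CPM in APOE4 Cre+ replicate 3 (52.5 to 54.4). In each group the mouse of title numbers 1 to 4 had the highest astrocyte-like Apoe. It was 89.8 CPM in APOE3 Cre-, 124 in APOE3 Cre+, 161 in APOE4 Cre- and 96.7 in APOE4 Cre+ mice. Apoe also passed in astrocyte-like cells between runs 1 and 3 by edgeR (log2 0.847), so this value follows the title-number run.

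The difference between the lines without Cre differed by sex (female minus male, log2, edgeR interaction) for Agt in astrocyte-like cells (-2.25) and Rgs5 in endothelial-like cells (-2.74) and capillary-like cells (-2.79). In capillary-like cells Rgs5, a pericyte marker, also differed by sex in the difference of the Cre effects (3.8). Each rests on 2 mice per sex and group. For Tshz2 in neuron-like cells the value was -7.57, but each Cre- group had only 1 male with enough cells and the spread came from other groups, so it does not show a difference by sex. Sex is nested in the title-number runs, and APOE4 Cre- replicate 3, a male of titles 1 to 4, had 10.8% pericyte-like cells against 1.09 to 2.97% in its group, so sex, run and pericyte RNA are not told apart for Rgs5.

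Between the APOE4 and APOE3 effects of Cre, 3 endothelial lists differed by camera, the heat shock chaperones (median log2 difference 0.48), caveolae and transcytosis (-0.37) and the immediate early and dissociation response (0.30). These list calls were lost with an estimated correlation (adjusted p = 0.0967, 0.207 and 0.714 with an estimated correlation).

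Clusters outside every comparison held 209 T or NK-like cells, 377 ependymal-like cells, 66 olfactory ensheathing or Schwann-like cells, 373 cells of an unnamed cluster led by Pcp4, Bloc1s1 and Fabp3 with a median mitochondrial share of 0.653%, and 222 cells of another unnamed cluster. A further 263 endothelial cells stayed unnamed, 214 with pericyte and smooth muscle genes and 49 with haemoglobin genes.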

How the results depend on the processing

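Limits of 30% and 40% and none on the mitochondrial share, sums without mitochondrial genes, leaving out cells over 10000 UMIs, and leaving out title numbers 1 to 4 were tests chosen after the data were seen. In the order APOE3 Cre, APOE4 Cre, their difference, the lines with Cre and the lines without, endothelial-like cells had 0, 0, 0, 25 and 25 genes, by edgeR. Without a filter on low counts these were 4, 2, 4, 66 and 83. Leaving out title numbers 1 to 4 gave 1 for APOE3 Cre, and females alone 1 for the difference. Between the lines, males alone gave 9 and 10, females alone 8 with Cre, 1000 genes per cell 7 and 9, capillary-like cells alone 15 with Cre, and thinned sums 16 without Cre. The other classes had 0, 0, 0, 273 and 355 pairs of gene and class, and 49, 285, 92, 873 and 1147 without the filter. For APOE3 Cre, leaving out title numbers 1 to 4 gave 2. For APOE4 Cre and the difference, this gave 3 and 1, DESeq2 5 and 1, the block of runs 4 and 1, 1 surrogate variable 3 and 1, males alone 6 and 1, females alone 9 and 1, a limit of 20% 1 and 1, and no limit 2 and 1. For APOE4 Cre alone, the 8 mice compared and no doublet removal gave 1 each. Between the lines with and without Cre, the block gave 419 and 607, males alone 63 and 75, females alone 84 and 128, and a limit of 20% 68 and 77. Without Cre the 8 mice gave 208, thinned sums 233 and a limit of 30% 202. Endothelial lists past camera were 2, 2, 3, 5 and 7, and with an estimated correlation or fry 0, 0, 0, 0 and 1. For APOE3 Cre they were 0 without the filter, 4 with the block, without a mitochondrial limit or without mitochondrial genes, 5 with 1 surrogate variable or thinned sums, and 1 at 20%, 30% or 1000 genes. For APOE4 Cre they were 4 with 1 surrogate variable or at 20%, and 1 at 30%, at 40% or without cells over 10000 UMIs. The difference had 5 without doublet removal or at 1000 genes and 1 without cells over 10000 UMIs, and the lines with Cre 3 on thinned sums and 9 without title numbers 1 to 4. Leaving out 1 mouse at a time gave 0 to 1 (1 without APOE3 Cre- replicate 1), 0 to 0, 0 to 0, 12 to 27 and 15 to 30 endothelial genes, 0 to 2, 0 to 2, 0 to 1, 169 to 363 and 203 to 378 pairs in the other classes, where APOE3 Cre had 2 without APOE3 Cre- replicate 1 and 1 without replicate 2, APOE4 Cre had 2 without APOE4 Cre- replicate 1 or 2 and 1 without APOE3 Cre- replicate 2, 3 or 4, APOE3 Cre+ replicate 2, APOE4 Cre- replicate 3 or APOE4 Cre+ replicate 3, and the difference had 1 without APOE3 Cre- replicate 1 or 3, APOE4 Cre- replicate 1 or 3 or APOE4 Cre+ replicate 1. It gave 1 to 6, 2 to 4, 2 to 7, 2 to 9 and 1 to 9 lists, and 0 to 0 shares. Apoe in endothelial-like cells between the lines without Cre (0.16) changed sign in females alone (-0.68), without title numbers 1 to 4 (-0.33) and without APOE4 Cre- replicate 3 (-0.33), passing in none, and was 0.55 without APOE4 Cre- replicate 4. The cause was not tested for these results. Mitochondrial limits of 5% and 10% kept 439 and 2018 cells and gave no value for genes or lists. At these limits 0 class shares passed, in a test that a change in 1 class alone could not pass. Of 112 named calls, 31 stayed past the threshold under every alternative that gave a value, and 0 reversed. Title numbers gave a block of runs, not labelled pairs.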

Other observations

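The counts over other splits of the mice were tests chosen after the results were seen.

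In capillary-like endothelial cells the coagulation and fibrinolysis list was higher in APOE4 Cre- than APOE3 Cre- mice, with a median log2 change of 0.65 and 7 of 8 members positive (adjusted p = 6.97e-06, and adjusted p = 0.0146 with an estimated correlation). Of its members 1 rose over all genes tested and 4 adjusted over the list alone. Capillary-like cells are part of the endothelial class, where this list passed in the same comparison, so this is not a separate result. In pericyte-like cells the immediate early and dissociation response passed for APOE4 Cre+ against APOE4 Cre-, with a median of 0.38 and 8 of 9 members positive (adjusted p = 3.38e-06, and adjusted p = 0.0206 with an estimated correlation), 0 passing over all genes and 3 adjusted over the list alone. In choroid plexus-like cells the unfolded protein response was lower in APOE4 Cre- mice, with a median of -0.23, 3 of 22 members falling over all genes and 11 adjusted over the list alone (adjusted p = 1.94e-05, and adjusted p = 0.191 with an estimated correlation). These list tests were not planned and were picked from many classes, lists and comparisons. They were not repeated on other splits of the mice.

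Of 42 pairs of gene and comparison called in several classes, 7 went in opposite directions, for 6 genes. Between the lines with Cre, Atf3 rose in endothelial-like cells (log2 1.55) and fell in choroid plexus-like cells (-1.46), and Nr4a3 rose in astrocyte-like (3.09) and fell in choroid plexus-like cells (-1.80). Pttg1 rose in neural progenitor-like cells with and without Cre (2.58 and 3.12) and fell in endothelial-like (-3.41 and -2.29), astrocyte-like and smooth muscle-like cells. In APOE4 mice endothelial Pttg1 was 0 to 3.34 CPM in 5 and 55.6 to 68.8 in 3 (APOE4 Cre+ replicate 4 and APOE4 Cre- replicates 2 and 3), which had the lowest progenitor values (69.4 to 148 against 181 to 287 CPM). Without Cre, Mndal rose in endothelial-like (1.99) and fell in pericyte-like cells (-1.91), Apod rose in choroid plexus-like (1.31) and fell in endothelial-like cells (-1.46), and S100a6 rose in choroid plexus-like (2.28) and fell in astrocyte-like cells (-0.71). Differences between these classes were not tested.

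Mouse Apoe, usually among the most abundant transcripts of astrocytes, averaged 64.4 to 99.8 CPM in astrocyte-like cells of the 4 groups, and whether the mouse gene is intact in these lines is not given in the sources used here.

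Between the lines, 1 of 35 splits of the 8 mice, the real one, gave as many endothelial genes. The real count was 25 with a highest other of 0 with Cre, and 25 and 6 without. The other classes also had 1 of 35 splits in each, 273 against a highest other of 122 with Cre and 355 against 50 without. A share of 1 in 35 is the smallest that these splits can give, so the counts speak against chance without excluding it. For the Cre comparisons the real count was 0, so every split gives as many and the counts say nothing on chance. In endothelial-like cells these were 35 of 35, 35 of 35 and 100 of 100 splits, with highest others of 3 for APOE3, 4 for APOE4 and 30 for their difference, and in the other classes 35 of 35 in each, with highest others of 277, 164 and 148. The split with 277 genes put both mice of title numbers 1 to 4 on 1 side and both of 13 to 16 on the other, that with 164 parted titles 7, 8, 11 and 12 from 3, 4, 15 and 16, and that with 148 put titles 1 to 4 on 1 side. Those with 122 and 50 genes between the lines parted titles 1 to 4 and 13 to 16 from the rest, and titles 1 to 8 from 9 to 16, and that with 4 endothelial genes the latter too. These splits follow the runs of title numbers and show a structure of the samples. With the runs as a block the real counts in the other classes were 4 for APOE4, 1 for the difference, and 419 and 607 between the lines, and in endothelial-like cells 34 and 35 between the lines. For lists in endothelial-like cells chance cannot be excluded, with 26 of 35 (real 2, highest other 11), 32 of 35 (2, 9), 85 of 100 (3, 12), 15 of 35 (5, 10) and 9 of 35 splits (7, 12) in the order of the comparisons. The median count of lists over the other splits was 3, 5, 5, 3.5 and 4 in that order. For the 3 Cre comparisons this median was above the real count.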
